A study of Mus musculus with 4 samples.

How the data were processed

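RNA from brain cortex of male SAMR1 mice treated with TCQA or water was hybridised to Clariom S mouse arrays, 2 per group and 4 in all, from 100 ng of RNA per array, per the submitters' design text. The deposited values are log2 signals per transcript cluster that the authors made with signal space transformation RMA (SST-RMA) in the Transcriptome Analysis Console 4.0.2, per the submitters' design text, and the submitters' processing notes name RMA and limma. RMA in general subtracts background, equalises the distributions of the arrays and combines the probes of a transcript cluster, so that the values carry no total or depth per array. The signal space transformation is meant to lessen the compression of differences, so fold changes can be larger than with plain RMA. The authors' stated filters on detection above background (0.05) and on the area under the curve of positive against negative controls (at least 0.7) rest on probe-level values and on their software's calls, which were not used here. The same area computed here from the control probe sets of the value table lay between 0.773 and 0.781 per array. The genome build is not given in the sources used here, and no coordinates are printed.

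The value table holds 28846 transcript clusters and control probe sets. Gene symbols came from the array's platform annotation, which gives 1 symbol for 19572 of them, several for 0 and none for 9274, of which 6640 were control probe sets and 2634 were transcript clusters that are unnamed here. Gene identifiers of all 19572 were matched to a table of RefSeq genes on GRCm38.p6, and no symbol changed. The 19572 named transcript clusters, standing for 19505 genes, were tested. Where 55 symbols had more than 1 transcript cluster, the brightest one stood for the gene in lists. Of 901 symbols in the fixed lists 804 were measured under those names.

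Groups were taken from the sample labels. Values were compared with limma 3.58.1 in R 4.3.3, as a linear model per transcript cluster with moderated 2-sided tests (lmFit and eBayes, no trend, no block), and p-values were adjusted by Benjamini-Hochberg over all 19572. The study's own criteria, an unadjusted p under 0.05 and a change of over 2-fold, were applied to the same model. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The tests ran over 26 pathway lists and, separately, over 16 lists of markers of cell types and neighbouring tissues, which the report names. The median standard error of a log2 change was 0.22, so that an unadjusted p of 0.05 corresponded to a log2 change of 0.52, or 1.43-fold.

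The tests, gene lists, named-gene rule and most alternatives were chosen before the data were examined. The rule named, among genes past the study's criteria whose brighter group was at or above the median signal and whose symbol was not a clone-type or model name, the 12 largest rises and 12 largest falls. It also named up to 4 members with the smallest p of each list described, and Actb, Gapdh and Hprt. Eomes, Cdhr1, Th and Calb2 in single arrays, and genes named only in the other observations, were chosen after their values were seen. Alternatives covered the prior, array weights, normalisation, centring, dim-signal filters, control probe sets, duplicate symbols, a replicate block and each array left out. The model was tested on simulated data for this comparison, 10 runs of 19572 transcript clusters with 200 changed. Transcript clusters were simulated independently of each other, with variances drawn from limma's fitted prior. A log2 change of 1.5 met the study's criteria in 95.5% of cases and the adjusted threshold in 52.1%, and one of 3 in 99.8% and 97.2%. A list shifted by 0.3 was called in 9 of 10 runs with the preset correlation, in 0 with an estimated one and in 1 with fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.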

Results

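Gene expression was measured in the brain cortex of male SAMR1 mice, a line bred as the normally ageing control of the senescence-accelerated mouse strains. The mice had been housed individually for 4 months from an age of 7 months. From 11 months of age one group received TCQA (tricaffeoylquinic acid, a plant polyphenol) by mouth at 5 mg/kg per day for 1 month, and the control group received purified water. Each group was represented by 2 Clariom S mouse arrays, 4 in all, with 19572 transcript clusters that carry a gene symbol. The labels do not say whether each array held RNA of 1 mouse or of a pool, so that p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision. The medians of the 4 arrays lay between 6.98 and 7.04 on the log2 scale. The negative control probe sets of the arrays had a median of 6.98 over all arrays, close to the median of 7.01 of the tested genes, and a 95th percentile of 11.06. Of the 12 largest rises and 12 largest falls named below, both group means exceeded that percentile for Trp53i11 and Ttr, so that the folds of the others are uncertain in size, and most so where a group mean lay below the median.

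The 4 cortex samples were close to each other, and samples of a group were no closer than the closest pair across groups. The TCQA arrays correlated with r = 0.9925 across genes and the water arrays with r = 0.9919, while pairs of a TCQA and a water array ranged from 0.9898 to 0.9927. The highest value joined TCQA 1 with water 2, and the lowest joined TCQA 2 with water 1. The first principal component held 42.5% of the variance and placed the TCQA arrays at 8.74 and 32.5 and the water arrays at -31.1 and -10.2. The control genes Actb, Gapdh and Hprt differed between TCQA and water by 0.02, -0.09 and 0.26 on the log2 scale, with SEs of 0.18, 0.18 and 0.20.

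The comparison of TCQA with water asked which cortical genes differ after a month of oral treatment. Among genes past the study's criteria, the transcripts furthest below the water level included several of choroid plexus epithelium. The largest fall was that of Ttr, the thyroid hormone and retinol carrier, which was 16.6-fold lower after TCQA. Folr1, the folate receptor of that epithelium, Kl, the ageing-related Klotho protein, and Kcnj13, a potassium channel, were 4.03-fold, 3.90-fold and 3.82-fold lower, although the TCQA means of Folr1 (6.35) and Kl (6.21) lay below the median of the negative controls, so that their folds are uncertain. Among the same genes, the transcripts furthest above it were Mrc1, the mannose receptor of macrophages at brain borders, at 2.85-fold, and Cdkn1a, a cell cycle inhibitor, at 2.71-fold. Trp53i11, Uprt, Med16 and Sfrp1 were between 2.30-fold and 2.58-fold higher. The water means of Mrc1 (6.56) and Sfrp1 (6.90) lay below the negative control median, so that their folds and rank are uncertain as well. No single gene passed the adjusted threshold. Without TCQA 2 the log2 changes were -2.08 for Ttr, -1.24 for Folr1 and 0.89 for Cdkn1a, against -4.06, -2.01 and 1.44 with all arrays. Without water 1 that of Kl was -1.20, against -1.97, and without TCQA 1 that of Mrc1 was 0.90, against 1.51.

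By the study's own criteria, an unadjusted p under 0.05 with a change of over 2-fold, 130 transcript clusters differed, 48 higher and 82 lower in TCQA. With limma and Benjamini-Hochberg adjustment 0 of 19572 passed, the smallest adjusted p being 0.642. An unadjusted p under 0.05 was reached by 1443 (681 higher, 762 lower), where chance alone gives 978.6. The excess depended on the variance prior: fitted over every probe set, controls included, it gave 984 of the same 19572. An ordinary t-test per gene without the empirical Bayes step also gave 0 after adjustment and 1322 with an unadjusted p under 0.05. Among the 48 higher genes 33 had a brighter group at or above the median signal, against 23 of the 82 lower ones, and 30 of the 82, but 2 of the 48, were olfactory, vomeronasal or taste receptor genes. The count of 130 became 369 without TCQA 1, 232 without TCQA 2, 218 without water 1 and 428 without water 2, and the lone array left in a group is assumed there to vary like the other group. Without TCQA 1, 2 genes passed limma's adjusted threshold, Ttr with a log2 change of -6.03 (adjusted p = 0.00279) and Eomes, a transcription factor of mitral and tufted cells, with 3.75 (adjusted p = 0.0163). Simulated arrays, with variances drawn from limma's fitted prior and genes drawn independently, gave a mean of 129.1 unchanged genes past the study's criteria (108 to 145). Of unchanged genes there, 4.94% had an unadjusted p under 0.05, against 7.37% of genes in the data. The simulation thus differs from the data and cannot show that the count of 130 is chance.

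Of the 12 genes with the largest falls, Ttr had levels of 15.42 and 11.46 in the TCQA arrays and of 17.72 and 17.27 in the water arrays, a log2 change of -4.06 (SE 1.12, transcript cluster TC1800000158.mm.2 on chromosome 18). Folr1 differed by -2.01 (SE 0.47), Kl by -1.97 (SE 0.56), Kcnj13 by -1.93 (SE 0.28, transcript cluster TC0100002762.mm.2 on chromosome 1) and Ecrg4, which encodes a secreted peptide precursor abundant in choroid plexus, by -1.95 (SE 0.43), with a TCQA mean of 5.54, also below the negative control median. Prkcd, a protein kinase C isoform strongly expressed in thalamus, was lower by a log2 change of -1.99 (SE 0.70), and Ecel1, a neuronal membrane peptidase, by -1.60 (SE 0.59). The other falls, Btbd35f18 (-1.63), Btbd35f3 (-1.27), Btbd35f9 (-1.21), Btbd35f19 (-1.17) and Btbd35f20 (-1.16), belong to 1 X-linked family of near-identical copies, among which probes cannot be assigned with certainty, and the TCQA means of Btbd35f18 (6.72), Btbd35f3 (6.27) and Btbd35f9 (6.96) lay below the negative control median. Adjusted p-values from limma lay between 0.642 and 0.673 for the 12 falls and the 12 rises. Prkcd lost its unadjusted p under 0.05 without TCQA 1 (-1.06) and without water 1 (-1.20), Ecel1 without TCQA 2 (-1.34) and without water 1 (-0.62), and Btbd35f20 without TCQA 1 (-0.98) and without water 1 (-0.64). Without TCQA 2, Ttr stood at -2.08 and Folr1 at -1.24, without water 1 Kl stood at -1.20, and without water 2 Ecel1 stood at -2.58.

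Of the 12 genes with the largest rises, Mrc1 differed by 1.51 on the log2 scale (SE 0.39), Cdkn1a by 1.44 (SE 0.37) and Ms4a15, a membrane protein gene, by 1.37 (SE 0.52), where the water means of Mrc1 (6.56) and Ms4a15 (5.96) lay below the negative control median. Trp53i11, named for its induction by the tumour suppressor Trp53, stood at 13.41 and 13.43 after TCQA and at 11.82 and 12.30 after water, a difference of 1.36 (SE 0.23, transcript cluster TC0200001448.mm.2 on chromosome 2). Prdm8, a transcriptional repressor of neurons, was higher by 1.34, Prss23, a serine protease, by 1.31 and Lrtm2, a leucine-rich repeat membrane protein, by 1.26. Uprt, a uracil phosphoribosyltransferase homologue, was 2.38-fold higher. Med16, a Mediator subunit, was higher by 1.22 (SE 0.21), Sfrp1, a secreted Wnt antagonist, by 1.20 (SE 0.21, with a water mean of 6.90, also below that median), and the vesicle-trafficking GTPases Rab4a and Rab2b by 1.22 and 1.17. Uprt and Med16 kept an unadjusted p under 0.05 and over 2-fold in every alternative setting tried. Ms4a15 lost its unadjusted p under 0.05 without TCQA 2 (0.52), without water 1 (1.53) and without water 2 (1.21), and stood at 2.22 without TCQA 1. Prss23 lost it without water 1 (1.02) and stood at 0.81 without TCQA 2, while Mrc1 stood at 0.90 without TCQA 1, Cdkn1a at 0.89 without TCQA 2 and Prdm8 at 0.86 without water 1.

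**Figure D1:**
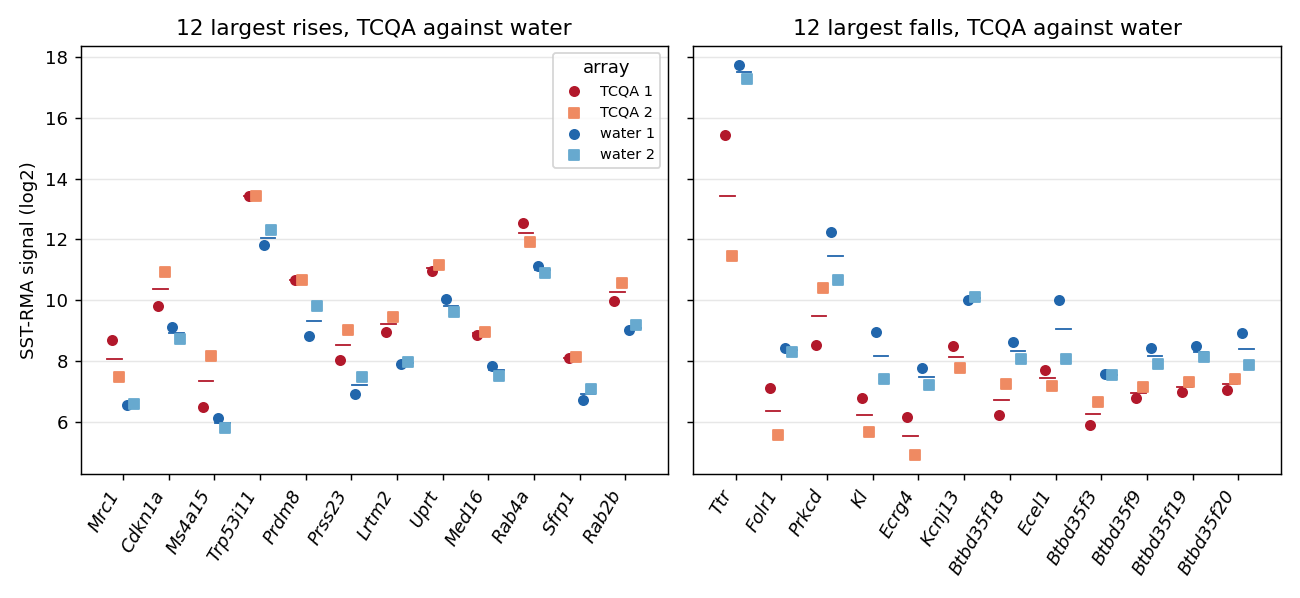
SST-RMA signal on a log2 scale of the 12 genes with the largest rises (left) and the 12 with the largest falls (right), 1 point per array with a short line at each group mean. The TCQA arrays of Ttr lie at 15.42 and 11.46 and the water arrays at 17.72 and 17.27, the widest distance in either panel, while Trp53i11 lies at 13.41 and 13.43 after TCQA.

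Markers of cell types and brain regions fixed before the data were examined asked whether the cortex samples differed in their tissue. Choroid plexus and ependyma markers were lower in TCQA, with 13 of 14 measured markers lower and a median log2 change of -0.80. Striatal markers were lower for 16 of 16 genes with a median of -0.64, myelinating oligodendrocyte markers for 12 of 14 with a median of -0.32, and thalamic markers for 11 of 16 with a median of -0.29. Excitatory neuron markers were higher for 13 of 15 genes, with a median of 0.29. These 5 of 16 lists passed limma's camera with a preset correlation of 0.01, at adjusted p-values of 5.09e-07, 9.56e-05, 0.0131, 0.0280 and 0.0145 in that order. With an estimated correlation the same lists had adjusted p = 0.764, adjusted p = 0.764, adjusted p = 0.783, adjusted p = 0.764 and adjusted p = 0.764. Under the estimated correlation and under fry, 0 lists passed and 0 had an unadjusted p under 0.05, against 7 with the preset one. Without water 1 the striatal (median -0.037), thalamic (-0.081) and excitatory neuron (0.091) lists no longer passed, and the test of the myelin list turned to the other direction (median -0.0755, limma's camera, adjusted p = 0.895). Without TCQA 1 the thalamic (-0.22) and excitatory neuron (0.28) lists did not pass. Without TCQA 2 the medians were -0.37 for striatum and -0.50 for thalamus, and without water 2 they were -1.10, -0.67, -0.53 and 0.47 for striatum, myelin, thalamus and excitatory neurons. The choroid plexus list passed in all 4 such fits, with a median of -0.50 without water 1.

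In the choroid plexus list 8 markers were lower with an unadjusted p under 0.05, and 8 passed when adjusted over the list alone, against 0 over all genes tested. Beside Ttr, Folr1 and Kl, these included F5, coagulation factor V, at -0.92 (SE 0.22; adjusted p = 0.0386 when adjusted over the list alone, limma), with both groups below the negative control median (5.21 and 6.13). Without TCQA 2, Ttr stood at -2.08 and Folr1 at -1.24, and without water 1 Kl stood at -1.20. The markers also differed within the water group, where water 1 lay above water 2 for 14 of 14 markers with a median of 0.44.

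Striatal and myelin markers were highest in water 1. Striatal markers, which mark dopamine-receptive spiny neurons, were higher in water 1 than in water 2 by a median of 1.16, myelin markers by 0.67 and thalamic markers by 0.46, although the mean of the thalamic list lay as far below the 4-array mean in TCQA 1 (-0.473) as above it in water 1 (0.478), while excitatory neuron markers were lower there by a median of -0.45. In the striatal list Sh3rf2 (-0.73), Adcy5 (-0.89), Pde10a (-0.59) and Ppp1r1b (-0.79) had the smallest p-values, the TCQA mean of Sh3rf2 (6.90) lay below the negative control median, 0 of 16 markers reached an unadjusted p under 0.05 with limma, and 0 passed when adjusted over the list alone. Without TCQA 1 these 4 genes reached an unadjusted p under 0.05, at -1.08, -1.08, -0.82 and -1.06, as they did without water 2, at -1.03, -1.47, -0.92 and -1.34. They did not without water 1, at -0.43, -0.31, -0.26 and -0.23, or without TCQA 2, at -0.38, -0.70, -0.37 and -0.51.

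Calls of single markers changed when arrays were left out. Mag, a myelin adhesion protein, differed by -0.67, the 1 myelin marker with an unadjusted p under 0.05 by limma, and lost it without TCQA 1 (-0.57), TCQA 2 (-0.77) or water 1 (-0.31), with a value of -1.03 without water 2. Fezf2, a transcription factor of deep-layer projection neurons, differed by 1.17 and lost its unadjusted p under 0.05 without TCQA 2 (1.01) and water 1 (0.44), with 1.90 without water 2. Rorb, of layer-specific excitatory neurons, differed by 0.54 and lost it without TCQA 1 (0.57), TCQA 2 (0.51) and water 1 (0.32). Synpo2 and Tcf7l2, of the thalamic list, differed by -0.71 and -0.86 and lost it without TCQA 1 (-0.61 and -0.67) and without water 1 (-0.48 and -0.54), and both groups of Synpo2 lay below the negative control median (5.78 and 6.49). When adjusted over the list alone, 0 markers of the myelin, excitatory and thalamic lists passed.

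Olfactory bulb markers set TCQA 2 apart. Eomes lay at 8.32 in TCQA 2 and at 4.38, 4.58 and 4.55 in TCQA 1, water 1 and water 2, and Cdhr1, a cadherin-related protein of mitral cells, lay at 8.61 there and at 5.67, 5.87 and 5.62 in the others. Th, the rate-limiting enzyme of dopamine synthesis, and Calb2, the calcium-binding protein calretinin, were 8.05-fold and 6.90-fold above the mean of the other 3 arrays. Calb2 lay at 11.27 there and at 9.47 in water 1, against 7.91 and 8.06 in TCQA 1 and water 2. The inhibitory neuron and thalamic lists also hold Calb2. The mean of the inhibitory neuron list was highest in TCQA 2 (10.56), against 9.96 in TCQA 1, 10.03 in water 1 and 9.86 in water 2. Eomes and Cdhr1 in the other 3 arrays, and Th in TCQA 1 (5.92) and water 2 (6.51), lay below the negative control median, so that folds against them are uncertain. Between the groups the olfactory bulb list had a median of 0.35 with an adjusted p of 0.119 by limma's camera, and it passed without TCQA 1 with a median of 0.63 (adjusted p = 1.52e-07), against -0.068 without TCQA 2. Gng13 was lower in TCQA 2 than in the other arrays, and Pcdh8 lay at 7.99 there against 8.28 in water 2.

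The other marker lists did not pass camera with the preset correlation. Inhibitory neuron markers had a median of 0.34 (limma's camera, adjusted p = 0.100) and passed without TCQA 1 with a median of 0.49, against -0.046 without TCQA 2 and 0.055 without water 2. Endothelial markers had a median of 0.22 (adjusted p = 0.0742), led by Slc2a1, the glucose transporter of the blood-brain barrier, at 0.77 (SE 0.19), while Emcn, an endothelial sialoprotein, was lower by -0.67, with both groups below the negative control median (6.11 and 6.78) and an unadjusted p under 0.05, which it lost without TCQA 2 (-0.58) and without water 1 (-0.49). The list median was 0.14 without TCQA 2, and the list passed in the upper 50 percent of signal (10 markers, median 0.29, adjusted p = 0.00661) and with a filter at the negative control median. Mural cell markers had a median of 0.25 (adjusted p = 0.0742) and passed without TCQA 2 with a median of 0.40, against 0.046 without TCQA 1, and under quantile normalisation (0.20). Microglia and macrophage markers were lower for 12 of 15 genes with a median of -0.075 (adjusted p = 0.379), although Mrc1 was among them, and passed without TCQA 1 with a median of -0.27, against 0.042 without TCQA 2, -0.041 without water 1 and -0.18 without water 2. Mrc1 itself stood at 0.90 without TCQA 1. Medians were -0.081 for oligodendrocyte precursors, -0.10 for hypothalamus, 0.17 for the 5 measured blood genes, -0.021 for meninges and fibroblasts, -0.024 for hippocampus and 0.0062 for astrocytes, with adjusted p-values between 0.596 and 0.905. Leaving out 1 array moved or reversed several of these medians, to 0.18 without water 1 and -0.19 without water 2 for oligodendrocyte precursors, 0.13 without water 1 for hypothalamus, -0.16 without TCQA 1 for blood, 0.11 without TCQA 1 for meninges, -0.26 without TCQA 1 and 0.16 without TCQA 2 for hippocampus and -0.14 without water 2 for astrocytes. In these lists 0 markers passed when adjusted over the list alone. Of 15 listed blood genes 5 were measured. Their mean lay between 5.11 and 5.42 on the arrays, below the negative control median, so that list says little about blood in the samples.

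**Figure D2:**
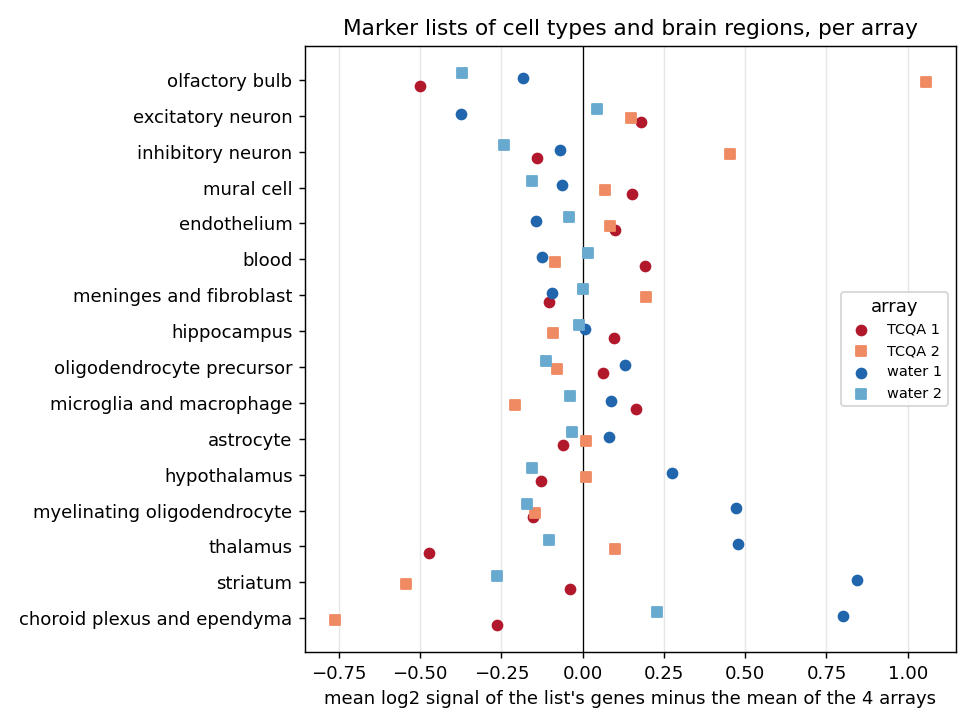
Mean log2 signal of each marker list in each of the 4 arrays, relative to the mean of the 4 arrays, 1 point per array. The choroid plexus and ependyma list lies at -0.265 and -0.763 in the TCQA arrays and at 0.80 and 0.228 in the water arrays, the striatal list lies at 0.844 in water 1, and the olfactory bulb list lies furthest right in TCQA 2.

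Pathway lists, also fixed before the data were examined, asked which functions differed in the treated cortex. Glucocorticoid response genes were higher after TCQA for 16 of 21 members, with a median log2 change of 0.24. Immediate early genes, which follow neuronal activity, were higher for 19 of 25 (median 0.20), neural progenitor and neurogenesis genes for 20 of 23 (median 0.14), and genes of synaptic vesicle release for 16 of 23 (median 0.14). These 4 of 26 lists passed limma's camera with the preset correlation, at adjusted p = 0.0236 for the glucocorticoid list and adjusted p = 0.0469 for each of the other lists. Each of the 4 had adjusted p = 0.737 with an estimated correlation, with which 0 of 26 lists passed, as under fry, and 0 had an unadjusted p under 0.05 in either, against 6 with the preset correlation. When adjusted over the list alone, 0 members of these 4 lists passed, as over all genes tested. Without TCQA 2 none of the 4 lists passed, with medians of 0.21, 0.13, 0.12 and 0.16. Without water 1 the immediate early (0.16), neurogenesis (0.17) and synaptic (0.0205) lists did not pass, and the glucocorticoid median was 0.36. Without water 2 the glucocorticoid (0.18) and neurogenesis (0.22) lists did not pass and the synaptic median was 0.25, and without TCQA 1 the synaptic list (0.12) did not.

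In the glucocorticoid list 6 members were higher with an unadjusted p under 0.05 and 0 were lower. Cdkn1a differed by 1.44, Pdk4, a kinase that restrains pyruvate oxidation, by 0.69 (SE 0.19), Fkbp5, a cochaperone of the glucocorticoid receptor, by 0.95 (SE 0.26) and Sult1a1, a sulfotransferase, by 0.59 (SE 0.19). Without TCQA 2, Cdkn1a stood at 0.89, and Pdk4 (0.61) and Fkbp5 (0.72) no longer had an unadjusted p under 0.05. Fkbp5 also lost it without water 2 (0.71), and Sult1a1 without TCQA 1 (0.53), water 1 (0.60) and water 2 (0.58). The striatal, thalamic and myelin markers that were high in water 1 were lower in TCQA, opposite to the glucocorticoid genes. Within the water group the glucocorticoid genes were also higher in water 1 than in water 2, by a median of 0.21.

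Among the immediate early genes 1 member had an unadjusted p under 0.05, Nr4a2, an orphan nuclear receptor, at 0.63 (SE 0.22), which lost it without TCQA 1 (0.62), TCQA 2 (0.64) and water 1 (0.40). The immediate early list was lowest in water 1, where it differed from water 2 by a median of -0.22, as were excitatory neuron markers (-0.45). In the neurogenesis list Vim, an intermediate filament of progenitors and astrocytes, differed by 0.85 (SE 0.27). Prom1, a progenitor surface protein, differed by 0.54 (SE 0.20) and Sox11, a transcription factor of immature neurons, by 0.48 (SE 0.20). Vim lost its unadjusted p under 0.05 without TCQA 2 (0.73) and water 2 (0.50), Prom1 without TCQA 2 (0.41), water 1 (0.54) and water 2 (0.53), and Sox11 without any 1 of the 4 arrays (0.38 to 0.57). The neurogenesis list also holds Eomes, which differed by 1.78 (SE 1.11) and was high in TCQA 2 alone, as was Cdhr1 of the olfactory bulb list.

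In the synaptic vesicle list Dnm1, the dynamin of vesicle retrieval, differed by 0.76 (SE 0.19), and the membrane fusion proteins Vamp2 and Snap25 by 0.58 (SE 0.19) and 0.50 (SE 0.18). Vamp2 lost its unadjusted p under 0.05 without TCQA 1 (0.63), TCQA 2 (0.53) and water 1 (0.52), and Snap25 without any 1 of the 4 arrays (0.46 to 0.53). Excitatory neuron markers, with which the list shares Slc17a7 and Sv2b, were lowest in water 1 as well.

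Other functions did not pass the list test. Over the 26 pathway lists, each adjusted on its own without correction across lists, 3 members passed when adjusted over the list alone. Fn1, the matrix protein fibronectin, was higher at 8.09 and 8.18 after TCQA against 7.03 and 7.06 after water, a log2 change of 1.09 (SE 0.18), and was the 1 of 27 extracellular matrix genes that passed when adjusted over the list alone (limma, Benjamini-Hochberg, adjusted p = 0.0223). Sfrp1 was the 1 of 36 Wnt genes that did so (limma, adjusted p = 0.0360 when adjusted over the list alone). Il1a, a pro-inflammatory cytokine, was 2.00-fold lower and was the 1 of 32 cytokine genes that did so (limma, adjusted p = 0.0407 when adjusted over the list alone). Its levels of 3.56 and 3.52 against 4.54 and 4.53 all lay below the median of the negative controls, so that its fold and its pass are uncertain. None of these 3 genes passed over all genes tested with limma, and each kept its unadjusted p under 0.05 whichever array was left out.

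Energy and stress lists did not pass camera. Mitochondrial biogenesis and sirtuin genes had a median of 0.16 (limma's camera, adjusted p = 0.0553) and cytosolic ribosomal protein genes were lower for 22 of 26 members with a median of -0.15 (adjusted p = 0.0827), a list that passed without TCQA 1 with a median of -0.26 (adjusted p = 0.0267), against -0.068 without TCQA 2, -0.094 without water 1 and -0.24 without water 2. In fry's test for changes in either direction, the mitochondrial list and the extracellular matrix list passed, each at adjusted p = 0.0225 (limma). Medians were 0.072 for glycolysis and glucose uptake, -0.042 for oxidative phosphorylation, 0.039 for NRF2 and antioxidant genes, 0.053 for cholesterol synthesis, 0.071 for heat shock and the unfolded protein response, 0.023 for autophagy and lysosome and 0.10 for the circadian clock, with adjusted p-values between 0.192 and 0.870. Without 1 array several of these moved, to 0.16 without water 2 for cholesterol synthesis and 0.053 without water 1 for oxidative phosphorylation. Medians became -0.012 for NRF2 and -0.015 for heat shock without water 2, and -0.00039 for the clock without water 1. Glycolysis ranged from 0.031 to 0.12 in such fits, and autophagy stood at -0.0054 without TCQA 1. Senescence and cell cycle arrest genes had a median of 0.12 (adjusted p = 0.584), and of 0.0039 without water 1, with Cdkn1a and Mdm2, the ubiquitin ligase of Trp53, at 1.44 and 0.68. Without TCQA 2, Cdkn1a stood at 0.89 and Mdm2 at 0.59, the latter no longer with an unadjusted p under 0.05.

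Signalling and immune lists did not pass camera either. Medians were 0.17 for extracellular matrix and perineuronal net, 0.076 for Wnt signalling, -0.092 for neurotrophins and growth factors, -0.090 for glutamate receptors, 0.13 for GABA receptors and metabolism, -0.036 for monoamine and acetylcholine signalling, -0.015 for neuropeptides and their receptors and -0.022 for voltage-gated ion channels. They were -0.078 for cytokines and NF-kB, 0.010 for the interferon response, -0.15 for complement and antigen presentation and -0.053 for amyloid and tau. Adjusted p-values from limma's camera for these 12 lists lay between 0.211 and 0.992. Without 1 array several medians moved or reversed, to -0.21 without water 1 and 0.052 without water 2 for glutamate receptors. Monoamine signalling stood at 0.15 without water 1. Without TCQA 2, extracellular matrix stood at 0.050, GABA receptors at 0.053 and cytokines at -0.031. Without water 2, neurotrophins stood at -0.21, the interferon response at -0.15 and amyloid and tau at 0.018. Wnt signalling stood at 0.045 without TCQA 1, and complement ranged from -0.25 to -0.10 in such fits. The median and mean differed in sign for the astrocyte, meningeal, hippocampal, interferon, monoamine, heat shock and neuropeptide lists, in which the test followed the mean except for the hippocampal, heat shock and neuropeptide lists.

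**Figure D3:**
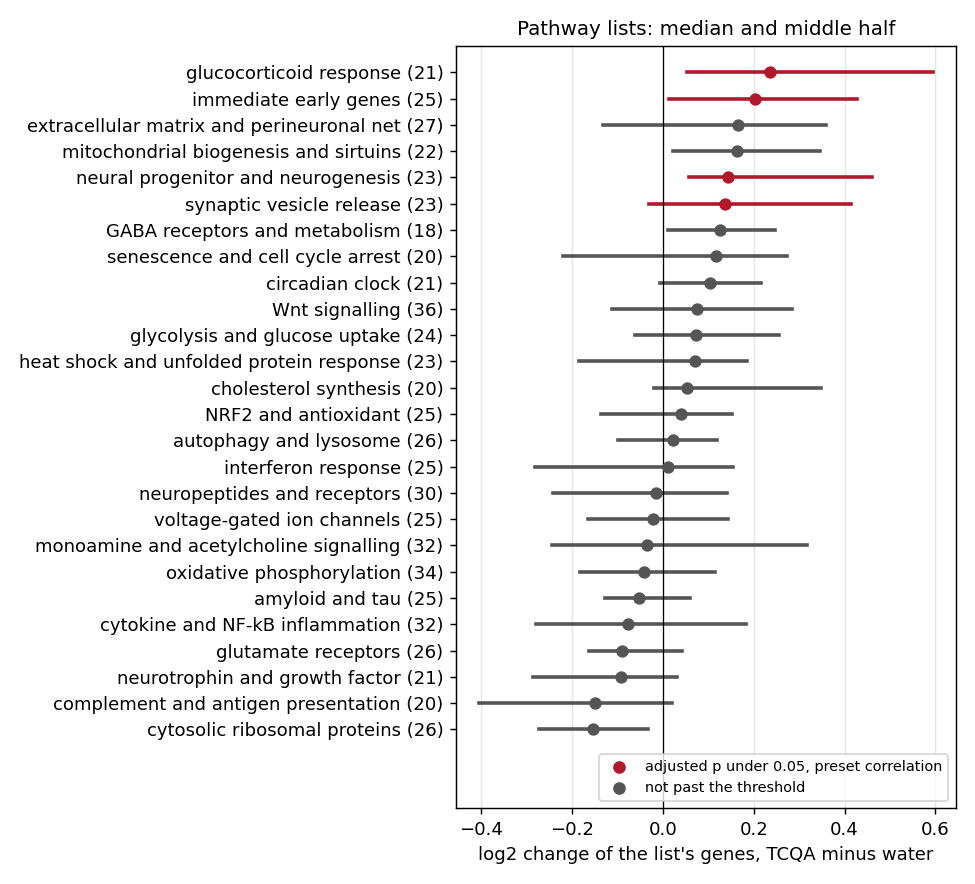
Median log2 change, TCQA minus water, of the 26 pathway lists (points) with the range of the middle 50 percent of their genes (lines) and the number of measured genes in brackets. The red lists, with glucocorticoid response at a median of 0.24 at the top, passed camera with the preset correlation of 0.01 and had adjusted p = 0.737 with an estimated correlation.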

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

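The fits with the choroid plexus or striatal marker mean as a covariate, the filter at the negative control median and the fit without marker genes were chosen after the data were examined. Unless another cause is named, the cause was not tested. Of 448 combinations of the 12 rises and 12 falls with a setting, 391 kept direction and side of the unadjusted threshold, 54 lost the threshold and 3 reversed. Of 705 for gene lists, 637 kept both, 49 lost and 12 gained the threshold and 7 reversed. The signal limits what can be read: negative controls had a median of 6.98, close to that of the genes. Of the 82 genes lower by the study's criteria, 59 had both groups below the median signal.

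The 130 genes past the study's criteria became 55 without variance moderation, 80 in the upper 70% and 44 in the upper 50% of signal, 56 with the negative control filter, where fewer genes are tested, and 499 with every probe set, where control probe sets are added. Leaving out 1 array gave 218 to 428. The choroid plexus covariate gave 871. It correlates at -0.886 with the groups and multiplied the median standard error by 2.20, so that every unadjusted call there exceeds 2-fold. The share of higher genes, 36.9%, was 68.2% in the upper 50%, 58.9% with the negative control filter and 48.1% with every probe set, and between 33.1% and 43.0% under quantile, loess and centring. Genes with an unadjusted p under 0.05 numbered 1443 (7.37% of those tested) and 871 (4.45%) with the choroid plexus covariate. With fewer genes tested they numbered 898 (9.18%) in the upper 50% and 942 (9.36%) with the negative control filter. The adjusted count by limma, 0, was 0 to 2 when 1 array was left out.

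The count of 4 pathway lists became 2 under quantile normalisation and 2 under loess, 1 in the upper 70%, 1 in the upper 50%, 1 with every probe set, 1 with the negative control filter, 0 with the choroid plexus covariate, 1 with the striatal one, 0 with an estimated correlation, 0 with fry, and 0 to 4 when 1 array was left out. In the upper 50% and with the negative control filter all 4 lists were lost (the glucocorticoid list with a median of 0.23), and the 1 list that passed was the ribosomal protein list. Under quantile and loess normalisation the lists that passed were the glucocorticoid and ribosomal ones, and in the upper 70%, with every probe set and with the striatal covariate the glucocorticoid one. The count of 5 marker lists became 6 under quantile normalisation, where the mural cell list was gained, and 4 with every probe set, where the thalamic list was lost. In the upper 50%, where too few choroid plexus markers were left to test that list, it became 4, and with the negative control filter 5. In both the excitatory neuron list was lost and the endothelial list gained (median 0.29 over 10 markers, lowest adjusted p = 0.00661 by limma's camera). It became 1 with the choroid plexus covariate, the striatal list in the other direction, 1 with the striatal one, the choroid plexus list, 0 with an estimated correlation, 0 with fry, and 1 to 6 when 1 array was left out. Simulated shifts of 0.3 were called in 0 of 10 runs with an estimated correlation. The counts of 0 lists with that test therefore say little about shifts of that size. The simulated genes were drawn independently, while the estimated correlation was 0.391 for the choroid plexus, 0.858 for the striatal and 0.791 for the myelin list. The simulation therefore cannot show whether the preset correlation of 0.01 holds for such lists.

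With the choroid plexus covariate these log2 changes reversed: Prss23 (-0.15), Kl (0.60), Ecel1 (0.86), Fezf2 (-0.62), Fmod (-0.23), S100a8 (1.37), Slc2a3 (-0.21), Casp1 (-0.36) and Stard4 (-0.017). So did list tests of immediate early genes (median -0.41), synaptic vesicle release (-0.058), excitatory neurons (-0.30), myelin (0.40), choroid plexus (-0.077) and striatum (1.01). By construction a list (choroid plexus with Kl, or striatum) loses its mean change under its own covariate, so those outcomes say nothing. The myelin list (medians -0.67 to -0.0755 with 1 array left out) reversed without water 1. The ribosomal protein list also passed without TCQA 1.

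The labels number the samples of both groups, but the deviations of same-numbered samples correlated at -0.0032, and the numbers were not taken as pairs. With a replicate block 130 genes met the study's criteria (48 higher, 82 lower, 129 shared with the fit without it), 1497 had an unadjusted p under 0.05, and 0 passed adjustment (limma, smallest adjusted p 0.647). Under the block 3 pathway lists passed, without synaptic vesicle release.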

Other observations

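The tests of the choroid plexus markers, of the olfactory bulb markers in TCQA 2 and of other splits of the arrays were chosen only after the result was seen. The families and genes in the next paragraphs were also chosen after their values were seen.

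Beyond the lists, the lower genes included members of multigene families, whose enrichment was not tested. Of 23 Btbd35f transcript clusters, an X-linked family of BTB-domain genes, 22 were lower in TCQA, 10 of them past the study's criteria, with a median log2 change of -0.93 (-0.95 after quantile normalisation), and a median difference of 0.35 between water 1 and water 2. Of 30 Y-linked predicted genes 25 were lower, 6 past the criteria, with a median of -0.48, while water 1 exceeded water 2 by a median of 0.45 and TCQA 1 exceeded TCQA 2 by 0.27, so that the difference within the water group was about as large. Of 11 Skint genes, an immunoglobulin-like family, 7 were lower and 2 met the criteria. Near-identical copies share probe sequence, so members of a family do not count as separate measurements.

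Of the 130 genes past the study's criteria, 39 (11 higher, 28 lower) also passed them whichever array was left out. Beside Trp53i11, Lrtm2, Uprt, Med16, Sfrp1 and Fn1, the higher ones were Gpr135, an orphan receptor (1.38), Stc2, a secreted glycoprotein hormone (1.17), Grasp, a scaffold protein of glutamate receptors (1.13), Mr1, an antigen-presenting molecule (1.11), and Ksr1, a scaffold of the Ras pathway (1.11). Of the falls named above, Ttr (-4.06), Folr1 (-2.01), Kl (-1.97), Ecrg4 (-1.95), Kcnj13 (-1.93) and Btbd35f18 (-1.63) were among the lower ones. Others outside the receptor families included Calml4, a calmodulin-like gene (-1.62), Cps1, the first enzyme of the urea cycle (-1.18), Tc2n (-1.30), Hscb, an iron-sulphur cluster cochaperone (-1.15), and Cfap65, of motile cilia (-1.11). Both group means of Gpr135, Stc2, Calml4, Cps1, Tc2n and Hscb lay below the median of the negative controls, as did the water mean of Mr1 and the TCQA mean of Cfap65, so that these values are uncertain.

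Choroid plexus and ependyma markers were lower in TCQA by limma's camera with the preset correlation (adjusted p = 5.09e-07). The list did not pass with an estimated correlation (adjusted p = 0.764) or with fry (adjusted p = 0.679). The markers' median change of -0.7988 lay below the range of random lists of like signal (-0.213 to 0.165), which argues against a shift of all genes at that level. Different amounts of plexus in the dissected samples may account for it: water 1 exceeded water 2 by a median of 0.4439, outside the range of random lists set for 2 pairs (-0.257 to 0.304), although TCQA 1 minus TCQA 2, at 0.226, lay inside its range (-0.253 to 0.272), and the test was widened to both pairs after that value was seen. An effect of TCQA on plexus cells stays open, since Ttr was below water by -2.08 and by -6.03 in the TCQA arrays, which differ by 3.953. Among 85 motile cilia genes outside the lists, tested as a sign of ependymal cells, the median of -0.02712 lay inside the random range (-0.0999 to 0.0552), with 4 genes lower and 0 higher past the study's criteria, and 8 lower against 1 higher with an unadjusted p under 0.05. By the bound set beforehand, a median inside the random range counts against ependymal cells as the source. By that bound the result counts against ependymal cells, and 44 of the 85 genes were lower, close to an even split. The genes with an unadjusted p under 0.05 were mostly lower, but their counts were no part of that bound and were not tested. They therefore do not overturn it, although a small contribution of ependymal cells is not excluded.

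Olfactory, vomeronasal and taste receptor genes, when pooled, were lower in TCQA, with 937 of 1452 lower, a median of -0.135 and 30 lower against 2 higher past the study's criteria. Olfactory receptors (699 of 1091 lower) and vomeronasal receptors (142 of 201 Vmn1r and 78 of 122 Vmn2r) carried this, while 20 of 35 Tas2r taste receptors were higher, with a median of 0.053. A shift of dim signal stays open: negative controls of like signal changed the other way, by a median of 0.05929, but the 3897 other genes in the lowest of 4 signal classes fell by a median of -0.0545, and after quantile normalisation less than 50 percent of the receptor change was left (-0.0613). The other splits of the arrays gave at most 12 receptor genes on 1 side, but 3 splits cannot give a share under 0.05, and an effect of TCQA was not tested separately.

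Glucocorticoid response genes were higher in TCQA by limma's camera with the preset correlation (adjusted p = 0.0236). The list did not pass with an estimated correlation (adjusted p = 0.737) or with fry (adjusted p = 0.437). With striatal markers as a covariate the list median was 0.2925, at the 99.99th percentile of random lists. The bound set beforehand reads this as against striatal tissue as the whole source. That percentile reflects only the choice of genes, however. Water 1 minus water 2, a pair without treatment, lay at the 100th percentile as well, so the fit cannot decide. Whether 1 array may carry the shift stays open: the 4 pairs of a TCQA and a water array lay at percentiles of 72.35, 100, 88.4 and 100, the lowest being TCQA 1 against water 1. Within the groups, water 1 minus water 2 had a median of 0.21, against 0.24 between the groups. TCQA 1 minus TCQA 2 had a median of -0.16, at a percentile of 3.7. An effect of TCQA, and differences in stress or in the time of sampling between mice, were not tested.

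Olfactory bulb tissue in the sample of TCQA 2 is a hypothesis for the high Eomes there, 14.0-fold above the mean of the other 3 arrays. Of the 9 other markers of that list 7 were higher in TCQA 2, with a median over the 9 of 0.4685, above the random range (-0.288 to 0.268), which is consistent with it, with Th, Cdhr1 and Calb2 at 8.05-fold, 7.42-fold and 6.90-fold. Gng13 (-0.497) and Pcdh8 (-0.0055) went the other way, and Nmb lay nearly as high in water 1 (5.9955) as in TCQA 2 (6.0401). Eomes and Cdhr1 in the other 3 arrays, and Th in TCQA 1 and water 2, lay below the median of the negative controls, so that these folds are uncertain.

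The 4 arrays can be split into 2 and 2 in 3 ways, and 1 of the 3, the real one, gave as many as 130 genes past the study's criteria, the highest other split giving 77. With 3 splits no share under 0.05 can be reached.

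In a fit over every probe set, 323 of 5222 negative controls (6.19%), 19 of 1324 positive controls (1.44%), 37 of 2634 unnamed transcript clusters (1.40%) and 120 of the 19572 tested genes (0.613%) met the study's criteria.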
